A study of Mus musculus with 2 samples.

How the data were processed

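Droplet single-cell RNA sequencing libraries of sorted lung cells were read from 1 joint matrix holding 14710 barcodes, 32285 genes and 2 hashtag features. The deposited values are raw UMI counts, whole numbers without normalization, per the file headers. Per the submitters' processing notes, they were made with Cell Ranger 6.1.2 on the mm10 build, and Seurat 4.2.0 was also named. The barcode suffix names the pool, per the labels, with suffixes 1 and 2 for neonatal and 3 and 4 for adult pools. The pools of 1 age were marked with 1 hashtag each, joined and loaded together, per the labels, and 0 barcodes were shared between pools of 1 age against 14 between ages. All columns were used, so columns not used came to 0. Gene coordinates came from the GENCODE M21 annotation of GRCm38, which matched 32235 of the 32285 gene identifiers, and are counted from 1.

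Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, and predicted doublets (Scrublet, per channel) and barcodes with over 20% of the other hashtag were left out. This left 12739 cells, with 105, 85, 20 and 14 doublets and 6, 0, 0 and 0 barcodes with both hashtags removed from neonatal pools 1 and 2 and adult pools 1 and 2. Counts were log-normalised, 2000 variable genes were chosen per age and merged to 2898 without cell cycle, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes. Leiden clustering at resolution 1 on 30 principal components and 15 neighbours gave 25 clusters, with no batch integration. Clusters were named from fixed marker lists by folds within pools. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9 was used.

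UMI counts were summed per pool and class, the pool being the replicate, and each class with 20 or more cells in every pool was tested between ages. Genes passed filterByExpr, sums were scaled by TMM, and edgeR 4.0.16 (glmQLFit with robust=TRUE, glmQLFTest) under R 4.3.3 gave Benjamini-Hochberg adjusted p values, with 0.05 as the threshold for a call. Total UMIs behind the 4 sums, rounded to 6 digits, were 5211490, 4981080, 2410670 and 1765910 for cDC1, 2424100, 1635610, 940042 and 866535 for cDC2, and 2210250, 2280800, 828269 and 766929 for mature DC. CPM are the UMIs of a gene over such a sum, scaled in the usual way, and values are raw ratios where an age held 1 to 3 UMIs of a gene, with exact 95% counting intervals, or lower bounds from 3 counts over the age where it held 0. The difference of age effects between cDC1 and cDC2 was tested as an interaction with pool as a block. Intervals and bounds cover counting error only.

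Gene lists with 5 or more tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a class, and again with an estimated correlation and with fry. With an estimated correlation, camera tests a list on the few residual degrees of freedom of 4 sums, which leaves it little power. That power was not tested on simulated data. The 25 functional lists and the marker lists partly overlap, so that single genes such as Nfkbia, Cxcl16 and Ube2c count in more than 1. Ube2c is on both the cell cycle list and the list of fetal and imprinted growth genes. No called functional list in the DC classes had a member at 0 in an age. Shares of cells were compared by two-sided exact permutation of the 4 pools. Free RNA was bounded from neutrophil transcripts in the classes other than neutrophils and classical monocytes, as the largest part of a gene's level in the higher age that it could supply.

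The named genes followed a fixed rule. It takes, per class, the 10 largest changes in each direction among called genes with at least 20 CPM in the higher age and both pools of 1 age above both of the other, without uncharacterised, haemoglobin and sex-linked genes. It adds up to 4 members of each list by smallest p, Zbtb46, and the 5 largest differences in each direction between cDC1 and cDC2. Of the genes the rule names, the text prints a part, and others, among top genes and members of called lists too, are left out for length. Gene lists, markers, the gene rule, tests and most alternatives were fixed before the data were examined.

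The tests were tested on simulated data made from the real means and depths with 200 changed genes. For cDC1 (9633 genes) the recovered shares were 44.9% at 1.5-fold, 75.0% at 2-fold, 100% at 4-fold, 100% at 8-fold. For cDC2 (8024 genes) they were 34.7% at 1.5-fold, 73.5% at 2-fold, 98.0% at 4-fold, 100% at 8-fold, and for mature DC (7448 genes) 18.8% at 1.5-fold, 67.4% at 2-fold, 95.7% at 4-fold, 100% at 8-fold. The interaction test recovered 89.5% at 4-fold (8284 genes). Data simulated without change gave 0 calls for each of the 3 classes.

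Alternatives tried were DESeq2 1.42.0 (Wald test, and its size factors within edgeR), other low-count filters, doublets kept, looser and stricter cell filters, Leiden resolutions 0.5 and 2, thinning to equal depth and cell numbers, leaving out each pool, the replicate number as a block, a fold of 1.5 as the null, leaving out ribosomal, mitochondrial and haemoglobin genes, and leaving out cycling cells. Added after seeing the data were fits of the clusters held by both ages, of as many cells drawn from the class, without genes open to free RNA, camera with an estimated correlation within those clusters, and of cDC2 without C1q-positive cells.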

Results

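Cells of the mouse lung that express, or descend from cells that expressed, Zbtb46 were profiled by droplet single-cell RNA sequencing at 7 days and at 8 weeks of age. Zbtb46 is a transcription factor of classical dendritic cells (DC), and in these mice Cre from its locus turns on YFP for good. Live CD45.2+ YFP+ cells were sorted from 2 pools of neonatal and 2 pools of adult lungs, each pool made from at least 5 mice, so n = 2 per age throughout. Gene UMIs came to 20346024 and 19549992 in neonatal pools 1 and 2 and to 8993471 and 8172362 in adult pools 1 and 2. After filtering, 4408, 4446, 2031 and 1854 cells were kept from these pools in that order, with median depths of 3714.5, 3558.5, 3168 and 3052 UMIs per cell. The question addressed is how lung DC differ between neonates and adults. Fold changes are neonatal over adult, so that a negative log2 value means higher in adult, and ± after a log2 value is its standard error, while ± after a CPM or a percentage is the SD of 2 pools.

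Age was bound to 2 other differences. The pools of 1 age were joined before loading, so that age and loading channel go together. Xist, the RNA that silences an X chromosome in females, stood at 709 and 603 CPM in neonatal pools 1 and 2 and at 0.235 and 0.129 CPM in the adult pools. The Y-linked Ddx3y stood at 0.525, 11.8, 69.7 and 76.6 CPM in the 4 pools. Neonatal pool 1 was thus female, neonatal pool 2 mostly female and the adult pools male. In neonatal pool 2, 305 cells had Y-linked and no Xist UMIs against 2852 with Xist and no Y-linked UMIs.

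DC made up 38.1% ± 3.54 in neonatal and 27.1% ± 2.51 in adult pools. Nonclassical monocytes were 31.7% ± 1.23 in neonatal and 15.1% ± 1.66 in adult pools, neutrophils 10.9% ± 2.63 in neonatal and 27.7% ± 1.28 in adult pools, and NK cells 1.31% ± 0.312 in neonatal and 13.9% ± 1.15 in adult pools. Classical monocytes were 9.94% ± 0.795 in neonatal and 10.4% ± 0.123 in adult pools, a difference smaller than the spread between neonatal pools. Among DC, cDC1 were 44.8% ± 1.58 in neonatal and 51.5% ± 3.31 in adult pools, cDC2 18.3% ± 3.53 in neonatal and 23.6% ± 1.28 in adult pools, and mature DC, which carry Ccr7 for migration to lymph nodes, 31.05% ± 2.61 in neonatal and 23.4% ± 1.52 in adult pools. Cells in separate proliferating cDC1 and cDC2 clusters count as DC, but not as cDC1 or cDC2 in these shares or in the tests below. With them, the cDC1 lineage held 869, 797, 322 and 239 cells in neonatal pools 1 and 2 and adult pools 1 and 2. Without them it held 783, 728, 316 and 231, so part of the lower neonatal cDC1 share comes from this split. For each class except classical monocytes (p = 1), both pools of 1 age lay above both of the other, with a two-sided exact permutation p of 0.333, the smallest that 2 pools against 2 can give. Shares depend on the sort, on cell recovery and on how clusters are drawn and named. The nonclassical and classical monocyte differences moved to 11.3 and 4.42 percentage points when cells were clustered and named anew with predicted doublets kept. These doublets were only 105, 85, 20 and 14 barcodes in neonatal pools 1 and 2 and adult pools 1 and 2. They were 2.32%, 1.88%, 0.975% and 0.749% of the barcodes that passed the gene, UMI and mitochondrial filters. Counting them in is thus too little to make up moves from 16.7 to 11.3 and from -0.436 to 4.42 points. Most of these moves would have to come from redrawn or renamed clusters, and which of these it was was not tested.

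**Figure D1:**
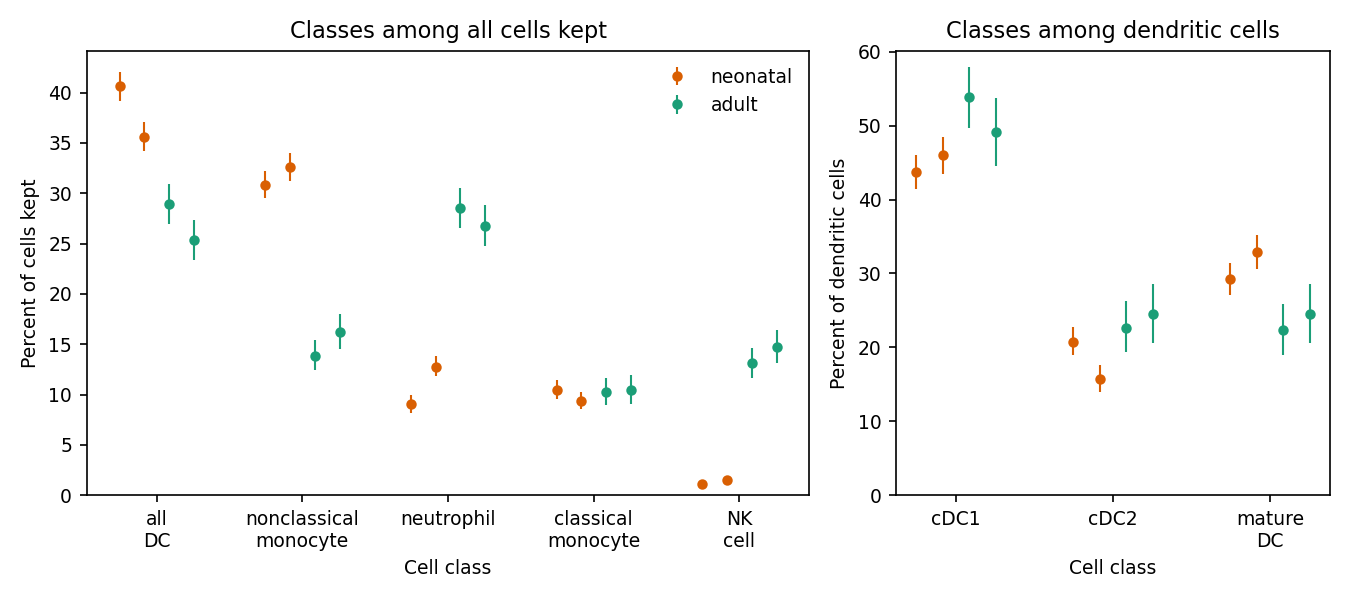
Percent of cells kept (left) and percent of dendritic cells (right) by cell class; each point is 1 pool, with its exact 95% binomial interval for counting error. NK cells were 1.09% and 1.53% in the neonatal pools and 13.1% and 14.7% in the adult pools.

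The cDC1 and the mature DC fell into different clusters at the 2 ages. Cluster 0 held 98.3% of neonatal but 21.02% of adult cDC1, and cluster 22, led by Cldn1, Epcam, Itgae, Plet1, Cd207 and Pcdh7, held 1.65% and 79.0%. Of mature DC, cluster 8 held 77.5% of neonatal and 6.098% of adult cells. Cluster 14, led by Ccl22, Fabp5, Apol7c, Il4i1, Nr4a3 and Aldh1a2, held 19.9% and 93.9%.

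cDC1, the DC that take up dead cells and present their antigens to CD8 T cells, were compared in 783 and 728 neonatal and 316 and 231 adult cells. Of 9859 genes tested, 2656 were called, 1171 higher in neonatal and 1485 higher in adult. Among them 823 changed by 2-fold or more, 258 of them higher in neonatal and 565 higher in adult. Both pools of 1 age lay above both of the other for 62.4% of the genes tested, where chance gives 33.3%, and 3596 genes had an unadjusted p under 0.05. Neonatal cells, almost all in cluster 0, expressed Igf2bp3, an RNA-binding protein of fetal and regenerating tissues, at 32.8 ± 4.64 CPM in neonatal and 1.55 ± 1.02 in adult (log2 4.43 ± 0.34, adjusted p = 2.0e-13; ENSMUSG00000029814, chromosome 6, 49085223 to 49214957, - strand, GRCm38). Adult cells, most of them in cluster 22, expressed the CD94 gene Klrd1, a lectin-like receptor known from NK cells, at 3.05 ± 0.514 CPM in neonatal and 219.9 ± 20.6 in adult (log2 -6.20 ± 0.14, adjusted p = 1.5e-29; ENSMUSG00000030165, chromosome 6, 129591782 to 129598775, + strand).

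Other genes higher in neonatal cDC1 were the kinase genes Dapk2 (35.0-fold, interval 11.8 to 171) and Yes1 (29.4-fold, interval 9.91 to 144), where adult sums held 3 UMIs each and counting intervals are given, Khdrbs3 (4.60 ± 0.38), Tcea3 (3.48 ± 0.26), Chchd10 (3.02 ± 0.26) and Elavl4 (2.91 ± 0.27) and the small GTPase gene Rhoh (2.40 ± 0.27). The lipid carrier gene Apoe (2.83 ± 0.21) stood higher too, but was no longer called with predicted doublets kept (log2 1.70, adjusted p = 0.256). The cystatin gene Stfa1, one of a family of near-identical copies, reached 20.9 CPM in neonatal cDC1 against 31929 CPM in neonatal neutrophils, and free RNA could supply up to 89.3% of that. Adult cDC1 stood higher in the protocadherin gene Pcdh7 (400.2-fold, interval 109.9 to 3319), itself a leading gene of cluster 22, Clec4b1 (-5.87 ± 0.31), Pir (-5.13 ± 0.27), Pdlim1 (-5.12 ± 0.16), Cd209a (-5.07 ± 0.29) and Emp1 (-4.79 ± 0.19), the homeobox gene Barx2 (-4.63 ± 0.26) and the chemokine receptor gene Ccr1 (-4.61 ± 0.34). Igha, the constant region of IgA heavy chains, stood at 0.489 ± 0.123 CPM in neonatal and 57.8 ± 7.19 in adult cDC1 and at no more than 2.60 CPM in the other adult classes tested.

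**Figure D2:**
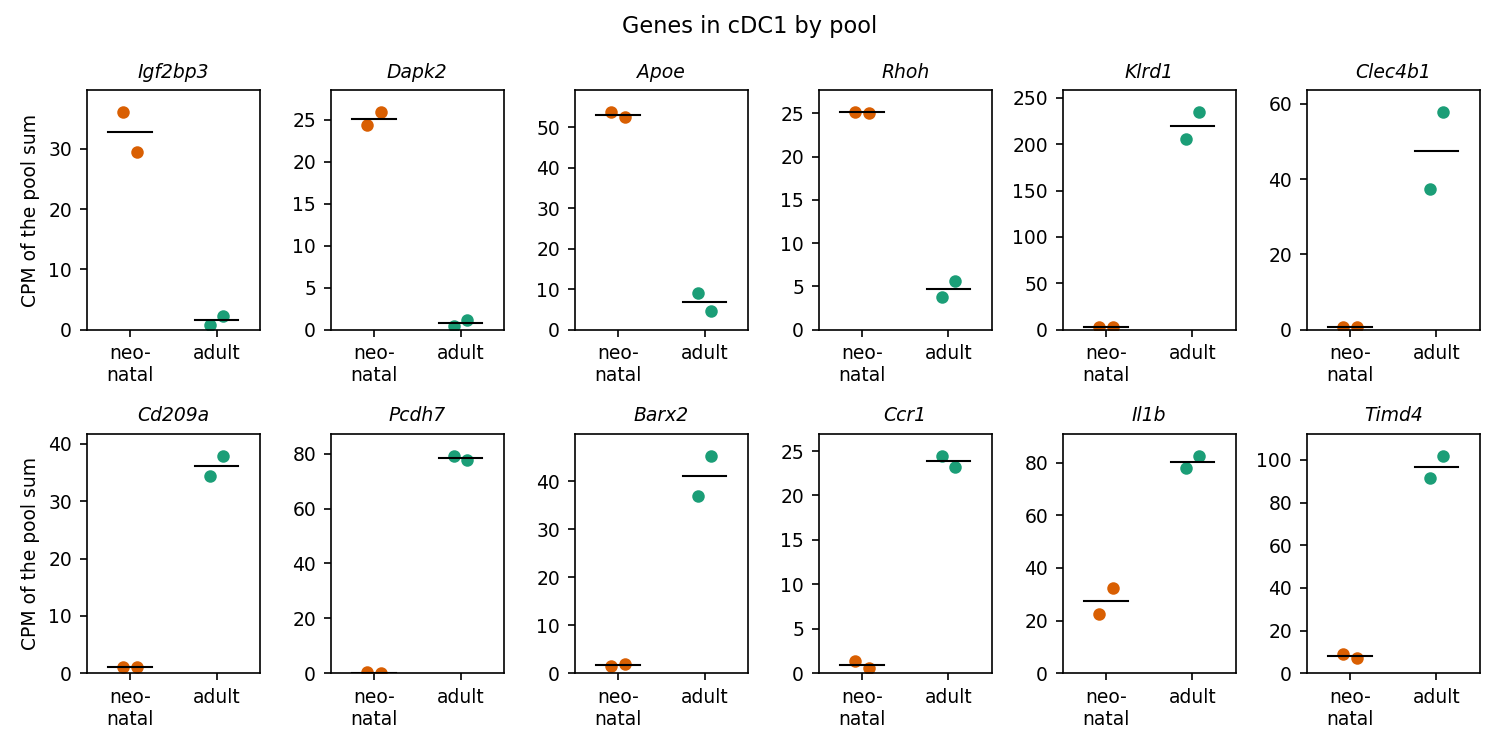
CPM of 12 genes in the summed counts of cDC1; each point is 1 pool and each line the mean of 2 pools. Klrd1 lay at 2.69 and 3.41 CPM in the neonatal pools and at 205 and 234 in the adult pools.

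Of 25 gene lists tested in cDC1, 14 were called, 3 higher and 11 lower in neonatal cells. None held with an estimated correlation, and fry, which asks whether a list moves one way on balance, called 18. The estimated correlation has little power with 4 sums, so the lack of calls with it decides little, here and in the other classes. MHC class II genes were lower in neonatal cells, with 1 higher and 14 lower of 19 tested, or 2 and 14 adjusted over the list alone (median -0.59, camera adjusted p = 1.1e-04, adjusted p = 0.212 with an estimated correlation). They included the invariant chain gene Cd74 (-0.59 ± 0.03), H2-Eb1 (-0.61 ± 0.03), H2-DMb1 (-0.70 ± 0.04) and H2-DMa (-0.61 ± 0.04). Costimulation genes had 0 higher and 8 lower of 9 tested, or 1 and 8 adjusted over the list alone (median -0.54, camera adjusted p = 0.00275, adjusted p = 0.212 with an estimated correlation). Tnfsf9 (-2.57 ± 0.28), Cd80 (-1.82 ± 0.26), Cd83 (-0.54 ± 0.08) and Cd86 (-0.48 ± 0.07) were among them. Genes of cross-presentation and dead-cell uptake had 3 higher and 11 lower of 18 tested, or 4 and 11 adjusted over the list alone (median -0.48, camera adjusted p = 0.00553, adjusted p = 0.212 with an estimated correlation). The uptake receptor genes Timd4 (-3.63 ± 0.15) and Axl (-2.89 ± 0.15) were lower in neonatal cDC1 and Rab43 (0.76 ± 0.06), needed for cross-presentation, was higher. Interferon-stimulated genes had 1 higher and 16 lower of 31 tested, or 1 and 18 adjusted over the list alone (median -0.55, camera adjusted p = 6.9e-05, adjusted p = 0.212 with an estimated correlation). Oasl2 (-3.72 ± 0.37), Ifi203 (-0.57 ± 0.07) and Bst2 (-0.59 ± 0.09) were among them.

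Inflammatory cytokine genes had 0 higher and 7 lower of 8 tested, or 0 and 7 adjusted over the list alone (median -1.65, camera adjusted p = 8.1e-04, adjusted p = 0.212 with an estimated correlation). Among them were Il1b (-1.60 ± 0.14), Tnfsf13b (-1.71 ± 0.15), Il1a (-4.91 ± 0.47) and Tnf (-2.71 ± 0.27), with up to 26.3% of the adult Il1b level within reach of free RNA. Chemokine genes had 0 higher and 5 lower of 11 tested, or 0 and 6 adjusted over the list alone (median -0.76, camera adjusted p = 0.00553, adjusted p = 0.212 with an estimated correlation). Ccl22 (-2.83 ± 0.11), Ccl6 (-1.76 ± 0.08) and Cxcl16 (-0.76 ± 0.06) were among them. NF-kB targets had 0 higher and 12 lower of 21 tested, or 1 and 12 adjusted over the list alone (median -0.56, camera adjusted p = 1.1e-04, adjusted p = 0.248 with an estimated correlation). Tnip3 (-4.39 ± 0.16), Nfkbia (-1.55 ± 0.06) and Traf1 (-1.80 ± 0.10) were among them. Immediate early and dissociation stress genes had 2 higher and 20 lower of 31 tested, or 3 and 23 adjusted over the list alone (median -0.55, camera adjusted p = 1.5e-05, adjusted p = 0.248 with an estimated correlation). Btg2 (-0.86 ± 0.04), Zfp36 (-1.01 ± 0.05), Junb (-0.88 ± 0.05) and Socs3 (-2.40 ± 0.16) were among them. Glucocorticoid-responsive genes had 0 higher and 9 lower of 14 tested, or 0 and 12 adjusted over the list alone (median -0.92, camera adjusted p = 1.5e-05, adjusted p = 0.212 with an estimated correlation). Txnip (-1.54 ± 0.08) and Tsc22d3 (-0.77 ± 0.10) were among them. Type 2 response genes had 1 higher and 9 lower of 14 tested, or 1 and 10 adjusted over the list alone (median -0.55, camera adjusted p = 1.1e-04, adjusted p = 0.212 with an estimated correlation), where Irf4 (-3.05 ± 0.39) and Il13ra1 (-0.86 ± 0.10) were lower and the Notch ligand gene Jag2 (1.87 ± 0.29) higher. Cholesterol and lipid genes had 3 higher and 13 lower of 28 tested, or 4 and 13 adjusted over the list alone (median -0.34, camera adjusted p = 0.0156, adjusted p = 0.248 with an estimated correlation), with Msmo1 (-1.70 ± 0.19) lower and Fabp5 (2.36 ± 0.26) higher. Fabp5 lost its call with predicted doublets kept (log2 2.82, adjusted p = 0.159) and Msmo1 in thinned cells (log2 -1.26, adjusted p = 0.124).

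The 3 lists higher in neonatal cDC1 concerned growth and respiration. Cell cycle genes had 27 higher and 1 lower of 40 tested, or 28 and 1 adjusted over the list alone (median 0.81, camera adjusted p = 3.6e-10, adjusted p = 0.212 with an estimated correlation), with Stmn1 (1.31 ± 0.12), Dut (1.03 ± 0.13) and Ube2c (1.79 ± 0.24) higher and Ccnd1 (-0.63 ± 0.06) lower. Oxidative phosphorylation genes had 55 higher and 1 lower of 65 tested, or 59 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 2.9e-14, adjusted p = 0.212 with an estimated correlation). Ndufa4 (1.28 ± 0.06), Cox6c (0.75 ± 0.05), Cox8a (0.62 ± 0.05) and Atp5g3 (0.80 ± 0.06) were among them. Fetal and imprinted growth genes had 4 higher and 0 lower of 5 tested, or 4 and 0 adjusted over the list alone (median 1.79, camera adjusted p = 7.0e-04, adjusted p = 0.212 with an estimated correlation), with Arid3a (1.63 ± 0.14) and Igf1r (2.92 ± 0.43) beside Igf2bp3. The other called member was Ube2c, which is also on the cell cycle list and whose value sets the median.

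Lists not called in cDC1 were MHC class I presentation (6 higher, 9 lower of 22, adjusted p = 0.107), chemokine and migration receptors (6 higher, 11 lower of 22, adjusted p = 0.0621), DC development factors (6 higher, 16 lower of 37, adjusted p = 0.0895), regulatory and inhibitory molecules (4 higher, 9 lower of 18, adjusted p = 0.373), pattern recognition (4 higher, 8 lower of 28, adjusted p = 0.805) and ribosomal proteins (13 higher, 22 lower of 65, adjusted p = 0.585). The same held for circadian clock (2 higher, 2 lower of 8, adjusted p = 0.432), glycolysis (5 higher, 5 lower of 20, adjusted p = 0.509), complement and antimicrobial (2 higher, 5 lower of 10, adjusted p = 0.460), T helper 1 and cytotoxic T cell instruction (2 higher, 5 lower of 11, adjusted p = 0.998) and sex-linked genes (2 higher, 2 lower of 6, adjusted p = 0.998). The T helper 1 list had a median of 0.17 and a mean of -0.37, and the signs of median and mean also differed in the complement and sex-linked lists. Within uncalled lists single genes changed. The MHC class I genes H2-D1 (-0.79 ± 0.04), H2-K1 (-0.91 ± 0.05) and B2m (-0.67 ± 0.04) were lower in neonatal cells, as was H2-Q7 (-2.30 ± 0.10), a member of a family of close copies. The profilin and flagellin sensor genes Tlr12 (2.13 ± 0.19) and Tlr11 (1.46 ± 0.17) and the galectin gene Lgals1 (1.84 ± 0.06) were higher.

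Markers of other cell types also moved in cDC1. cDC2 markers had 2 higher and 13 lower of 16 tested, or 2 and 13 adjusted over the list alone (median -1.76, camera adjusted p = 4.5e-06, adjusted p = 0.171 with an estimated correlation), so that adult cDC1 held more of most transcripts on this list than neonatal cDC1. Cd24a (394.6 against 126.2 CPM), Clec12a (249.0 against 167.0) and Ltb4r1 (221.1 against 215.6) stood higher in adult cDC1 than in adult cDC2 taken at resolution 2. At that resolution these genes thus did not mark adult cDC2 against adult cDC1, Ltb4r1 being nearly level, while the rest of the 13 stood lower in cDC1. The split depends on how cDC2 are drawn. Klrd1, at 219.9 CPM in adult cDC1, stood above the adult cDC2 class tested here (195.4) and below cDC2 at resolution 2 (272.1). These gaps were not tested. cDC1 markers had 14 higher and 1 lower of 19 tested, or 14 and 1 adjusted over the list alone (median 0.35, camera adjusted p = 1.9e-04, adjusted p = 0.306 with an estimated correlation). Markers of proliferating cells had 13 higher and 2 lower of 16 tested, or 13 and 2 adjusted over the list alone (median 1.07, camera adjusted p = 4.5e-06, adjusted p = 0.171 with an estimated correlation), and those of nonclassical monocytes 1 higher and 5 lower of 8 tested, or 1 and 5 adjusted over the list alone (median -0.66, camera adjusted p = 0.00734, adjusted p = 0.482 with an estimated correlation). Markers of plasmacytoid DC had 1 higher and 4 lower of 7 tested, or 1 and 4 adjusted over the list alone (median -0.59, camera adjusted p = 0.0450, adjusted p = 0.361 with an estimated correlation). The erythroid list was called (camera adjusted p = 0.0210, adjusted p = 0.361 with an estimated correlation) although none of its 5 tested genes was.

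Within cluster 0, with 771 and 715 neonatal and 69 and 46 adult cDC1, 525 genes were called. Of these, 458 were also called in the whole class. As many cells drawn from the whole class gave 958 called genes. The adult excess of Klrd1 (log2 -5.17), Clec4b1 (-5.49), Pdlim1 (-3.80), Timd4 (-2.93) and Il1b (-2.53) and the neonatal excess of Igf2bp3 (3.67) and Lgals1 (2.82) were called there. Nfkbia (-0.80, adjusted p = 0.626), Socs3 (0.12, adjusted p = 0.948), Cd80 (-0.0166, adjusted p = 0.997), Stmn1 (0.85, adjusted p = 0.606) and Tlr11 (0.38, adjusted p = 0.514) were not. Of 74 named genes called in the class, 47 were called within cluster 0, and of the 27 that were not called or not tested there, 7 were not called in as many drawn cells either. Ccl22 was among these 7 (adjusted p = 0.699 within cluster 0 and 0.501 in the drawn cells). Tnf was too, not tested within cluster 0 and with an adjusted p of 0.277 in the drawn cells. With the preset correlation, MHC class II (adjusted p = 6.6e-04), interferon-stimulated (7.7e-09) and inflammatory cytokine (0.0169) genes stayed lower in neonatal cells within cluster 0. With an estimated correlation none of these 3 was called there (adjusted p = 0.417, 0.417 and 0.486). Costimulation (0.113), chemokine (0.919) and NF-kB (0.456) lists were not called there with either.

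cDC2, the DC that present antigen chiefly to CD4 T cells, were compared in 372 and 250 neonatal and 133 and 115 adult cells. Of 8274 genes tested, 1307 were called, 531 higher in neonatal and 776 higher in adult. Among them 444 changed by 2-fold or more, 195 of them higher in neonatal and 249 higher in adult. Both pools of 1 age lay above both of the other for 56.9% of the genes tested, where chance gives 33.3%, and 2142 genes had an unadjusted p under 0.05. The mannose receptor gene Mrc1 was higher in adult cells, at 31.4 ± 11.8 CPM in neonatal and 293 ± 10.6 in adult (log2 -3.42 ± 0.14, adjusted p = 2.5e-116; ENSMUSG00000026712, chromosome 2, 14229392 to 14332057, + strand). Part of the class resembled macrophages, and without cells holding any C1q UMI Mrc1 stood at log2 -4.79 (adjusted p = 3.6e-27). The adrenergic receptor gene Adra2a was higher in neonatal cells, at 125 ± 0.483 CPM in neonatal and 7.63 ± 4.26 in adult (log2 3.85 ± 0.25, adjusted p = 1.3e-49; ENSMUSG00000033717, chromosome 19, 54044151 to 54048982, + strand).

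Neonatal cDC2 also stood higher in the cadherin gene Cdh1 (3.97 ± 0.38), the nestin gene Nes (3.66 ± 0.34), Igf2bp3 (3.60 ± 0.41), Enah (27.6-fold, interval 9.30 to 135) and Socs2 (49.4-fold, interval 8.68 to 1968), a suppressor of cytokine signalling. The chemokine receptor gene Cxcr2 (at least 12.6-fold higher) and Erc2 (at least 12.3-fold higher) had no UMI in adult cDC2, so these are bounds from 3 counts over the adult sums. Adult cDC2 stood higher in F13a1 (-4.13 ± 0.39), Cd72 (-3.18 ± 0.25), Klra17 (-3.09 ± 0.27) and Chd3 (-2.97 ± 0.31), of which Klra17 belongs to a family of similar receptors. Ecm1 (-3.22 ± 0.43) was higher in adult cells as well, but lost its call in several alternatives, such as with predicted doublets kept, where the fold stayed (log2 -3.19, adjusted p = 0.212). Very small p values in this class rest on a spread shared across genes and not on 4 pools alone.

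Of 25 lists tested in cDC2, 14 were called, 3 higher and 11 lower in neonatal cells, none of them with an estimated correlation and 10 by fry. MHC class II genes had 0 higher and 12 lower of 17 tested, or 0 and 13 adjusted over the list alone (median -0.59, camera adjusted p = 2.6e-06, adjusted p = 0.303 with an estimated correlation). H2-Eb1 (-1.08 ± 0.03), H2-Aa (-0.93 ± 0.03), H2-Ab1 (-0.87 ± 0.03) and Cd74 (-0.79 ± 0.02) were among them. MHC class I genes had 0 higher and 11 lower of 22 tested, or 0 and 13 adjusted over the list alone (median -0.34, camera adjusted p = 4.9e-05, adjusted p = 0.303 with an estimated correlation). H2-D1 (-0.97 ± 0.06), H2-K1 (-0.97 ± 0.07), B2m (-0.84 ± 0.06) and H2-T23 (-1.26 ± 0.11) were among them. Interferon-stimulated genes had 1 higher and 10 lower of 28 tested, or 1 and 15 adjusted over the list alone (median -0.67, camera adjusted p = 1.8e-05, adjusted p = 0.303 with an estimated correlation). Ifitm3 (-1.65 ± 0.07) and Isg15 (-1.91 ± 0.24) were among them. T helper 1 and cytotoxic T cell instruction genes had 0 higher and 4 lower of 7 tested, or 0 and 6 adjusted over the list alone (median -0.64, camera adjusted p = 0.00258, adjusted p = 0.303 with an estimated correlation). Cxcl16 (-1.33 ± 0.14) and Ifngr1 (-0.51 ± 0.10) were among them. Chemokine and migration receptor genes had 2 higher and 8 lower of 18 tested, or 2 and 11 adjusted over the list alone (median -0.49, camera adjusted p = 0.0109, adjusted p = 0.351 with an estimated correlation). Ccrl2 (-1.46 ± 0.15), Cx3cr1 (-1.52 ± 0.19) and Ccr2 (-0.57 ± 0.08) were among them. Inflammatory cytokine genes had 1 higher and 3 lower of 8 tested, or 1 and 6 adjusted over the list alone (median -0.81, camera adjusted p = 0.00563, adjusted p = 0.303 with an estimated correlation). Il1b (-1.23 ± 0.12) and Tnfsf13 (-2.04 ± 0.40) were among them.

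NF-kB targets had 1 higher and 7 lower of 21 tested, or 1 and 7 adjusted over the list alone (median -0.25, camera adjusted p = 0.00136, adjusted p = 0.373 with an estimated correlation). Nfkbia (-0.89 ± 0.08), Tnip3 (-0.99 ± 0.10) and Nfkbiz (-1.19 ± 0.14) were among them. Immediate early and dissociation stress genes had 3 higher and 17 lower of 31 tested, or 3 and 19 adjusted over the list alone (median -0.57, camera adjusted p = 1.6e-05, adjusted p = 0.303 with an estimated correlation). Fos (-1.49 ± 0.06), Btg2 (-1.41 ± 0.07), Junb (-1.11 ± 0.06) and Zfp36 (-1.05 ± 0.06) were among them. Glucocorticoid-responsive genes had 0 higher and 5 lower of 14 tested, or 0 and 7 adjusted over the list alone (median -0.58, camera adjusted p = 1.9e-04, adjusted p = 0.303 with an estimated correlation). Txnip (-1.90 ± 0.11) and Dusp1 (-0.73 ± 0.08) were among them. Cholesterol and lipid genes had 1 higher and 7 lower of 26 tested, or 1 and 7 adjusted over the list alone (median -0.39, camera adjusted p = 0.00990, adjusted p = 0.303 with an estimated correlation). Npc2 (-0.84 ± 0.08) was among them. Ribosomal protein genes had 4 higher and 43 lower of 65 tested, or 6 and 50 adjusted over the list alone (median -0.17, camera adjusted p = 4.6e-04, adjusted p = 0.351 with an estimated correlation). Rpl10 (-0.52 ± 0.05) and Rps9 (-0.38 ± 0.04) were among them. The lists higher in neonatal cDC2 were again growth and respiration. Cell cycle genes had 24 higher and 1 lower of 33 tested, or 28 and 1 adjusted over the list alone (median 1.31, camera adjusted p = 4.5e-13, adjusted p = 0.303 with an estimated correlation). Stmn1 (1.84 ± 0.18), Mki67 (1.53 ± 0.23) and Birc5 (1.71 ± 0.27) were among them. Oxidative phosphorylation genes had 25 higher and 0 lower of 65 tested, or 34 and 0 adjusted over the list alone (median 0.26, camera adjusted p = 2.6e-06, adjusted p = 0.303 with an estimated correlation). Ndufa4 (0.74 ± 0.11), Atp5g3 (0.78 ± 0.11) and Cox6c (0.49 ± 0.09) were among them. Fetal and imprinted growth genes had 3 higher and 0 lower of 5 tested, or 3 and 0 adjusted over the list alone (median 1.10, camera adjusted p = 0.00106, adjusted p = 0.303 with an estimated correlation). Ube2c (log2 2.11), which is also on the cell cycle list, was among them.

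Costimulation (3 of 9 lower, adjusted p = 0.266) and chemokine genes (7 of 12 lower, adjusted p = 0.108) were not called as lists in cDC2. Single genes of uncalled lists were higher in neonatal cells, among them the galectin gene Lgals1 (1.08 ± 0.07) and the STAT5 target Cish (2.10 ± 0.20). Of 9 marker lists tested in cDC2, 8 were called. Lower in neonatal cDC2 were markers of classical monocytes (0 higher and 6 lower of 7, adjusted p = 5.9e-04 and 0.268 with an estimated correlation), interstitial macrophages (0 higher and 6 lower of 14, adjusted p = 0.0154 and 0.422 with an estimated correlation), plasmacytoid DC (0 higher and 4 lower of 5, adjusted p = 0.00108 and 0.268 with an estimated correlation), nonclassical monocytes (1 higher and 3 lower of 9, adjusted p = 0.0461 and 0.334 with an estimated correlation) and cDC2 themselves (3 higher and 8 lower of 17, adjusted p = 0.00686 and 0.268 with an estimated correlation). Higher were markers of proliferating cells (10 higher and 0 lower of 13, adjusted p = 3.6e-06 and 0.304 with an estimated correlation), cDC1 (6 higher and 1 lower of 15, adjusted p = 0.00686 and 0.304 with an estimated correlation) and mature DC (5 higher and 2 lower of 20, adjusted p = 0.0152 and 0.333 with an estimated correlation). Without cells holding any C1q UMI, 1019 genes and 13 lists were called in cDC2, while in the full class no list held with an estimated correlation.

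Mature DC were compared in 523 and 521 neonatal and 131 and 115 adult cells, mostly cluster 8 in neonates and cluster 14 in adults. Of 7701 genes tested, 2704 were called, 1311 higher in neonatal and 1393 higher in adult. Among them 1227 changed by 2-fold or more, 616 of them higher in neonatal and 611 higher in adult. Both pools of 1 age lay above both of the other for 66.9% of the genes tested, where chance gives 33.3%, and 3342 genes had an unadjusted p under 0.05. The Src family kinase gene Yes1 stood at 188 ± 13.9 CPM in neonatal and 8.19 ± 1.33 in adult (log2 4.44 ± 0.24, adjusted p = 1.1e-12; ENSMUSG00000014932, chromosome 5, 32611171 to 32687057, + strand). The cytokine gene Il1b stood at 16.7 ± 2.58 CPM in neonatal and 239.9 ± 38.8 in adult (log2 -3.91 ± 0.17, adjusted p = 3.7e-14; ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, - strand), but lost its call with predicted doublets kept (log2 -2.57, adjusted p = 0.0774) and at resolution 2 (log2 -2.03, adjusted p = 0.0547). Neonatal cells stood higher in the microtubule gene Map1b (40.8-fold, interval 7.19 to 1627), Cdk5r1 (34.0-fold, interval 11.5 to 166), Wdr90 (4.06 ± 0.40) and Cpne8 (3.82 ± 0.40) and the growth factor gene Csf1 (16.9-fold, interval 5.68 to 83.1). Adult cells stood higher in the Notch regulator gene Dtx1 (at least 60.1-fold higher) and in Barx2 (at least 46.0-fold higher), both without a UMI in neonatal cells, in Ms4a4c (-4.85 ± 0.37), Cd72 (-4.54 ± 0.55) and Cd7 (31.9-fold, interval 10.0 to 162), and in the TIM-3 gene Havcr2 (-3.91 ± 0.30).

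Of 24 lists tested in mature DC, 5 were called, 1 higher and 4 lower in neonatal cells, none with an estimated correlation and 11 by fry. MHC class II genes had 0 higher and 13 lower of 18 tested, or 0 and 13 adjusted over the list alone (median -1.32, camera adjusted p = 4.3e-06, adjusted p = 0.530 with an estimated correlation). H2-Ab1 (-2.21 ± 0.09), Cd74 (-1.60 ± 0.08), H2-Eb1 (-1.31 ± 0.08) and H2-Aa (-0.97 ± 0.08) were among them. MHC class I genes had 11 higher and 1 lower of 22 tested, or 12 and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.0103, adjusted p = 0.530 with an estimated correlation), with Tap1 (1.06 ± 0.11), Nlrc5 (1.15 ± 0.16) and Tapbp (0.83 ± 0.10) higher in neonatal cells. Ribosomal protein genes had 0 higher and 62 lower of 65 tested, or 0 and 65 adjusted over the list alone (median -0.60, camera adjusted p = 8.6e-14, adjusted p = 0.530 with an estimated correlation). Rpl8 (-1.12 ± 0.08) and Rpl5 (-1.07 ± 0.09) were among them. Oxidative phosphorylation genes had 0 higher and 35 lower of 65 tested, or 0 and 39 adjusted over the list alone (median -0.39, camera adjusted p = 7.8e-06, adjusted p = 0.530 with an estimated correlation). Atp5h (-0.86 ± 0.09) and Ndufa2 (-0.83 ± 0.14) were among them. Cholesterol and lipid genes had 3 higher and 14 lower of 27 tested, or 3 and 14 adjusted over the list alone (median -0.88, camera adjusted p = 0.00326, adjusted p = 0.530 with an estimated correlation), with the sterol synthesis genes Hmgcs1 (-1.78 ± 0.13), Idi1 (-1.28 ± 0.10) and Msmo1 (-2.03 ± 0.20) lower and the sterol exporter gene Abcg1 (1.52 ± 0.15) higher. Whether the opposite signs of oxidative phosphorylation in cDC1 and mature DC differ was not tested.

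Other genes of mature DC also changed. The transcription factor gene Irf8 (2.01 ± 0.12) and the receptor genes Il4ra (1.76 ± 0.14) and Il15ra (1.60 ± 0.14) were higher in neonatal cells, and Cd86 (-1.14 ± 0.12), Il6 (-3.76 ± 0.59) and Btg2 (-2.01 ± 0.12) were lower. Costimulation genes as a list had 5 higher and 2 lower of 11 (adjusted p = 0.630), and cell cycle genes 3 higher and 3 lower of 17 (adjusted p = 0.702). Of the marker lists, cDC2 markers alone were called, with 1 higher and 7 lower of 13 tested, or 1 and 7 adjusted over the list alone (median -0.92, camera adjusted p = 0.0365, adjusted p = 0.424 with an estimated correlation).

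Many of these differences lay between clusters. Within cluster 14, with 93 and 115 neonatal and 125 and 106 adult cells, 598 genes were called against 1763 for as many cells drawn from the whole class. Of these, 437 were also called in the class. Of 46 named genes called in the class, 25 were called within cluster 14, and of the 21 that were not called or not tested there, 2 were not called or not tested in as many drawn cells either. Il1b (log2 -3.36), Havcr2 (-3.12), H2-Ab1 (-0.69) and Hmgcs1 (-0.93) stayed lower in neonatal cells and Yes1 (2.39) higher. The MHC class I gene H2-Q4, of a family of close copies, was higher in neonatal cells in the class (0.90 ± 0.11) but lower within cluster 14 (-0.82, adjusted p = 0.00132). Irf8 (-0.40, adjusted p = 0.117) and Il4ra (-0.40, adjusted p = 0.391) were not called there. Of the ribosomal genes, Rpl8 (-0.0252, adjusted p = 0.922) and Rps6 (-0.14, adjusted p = 0.383) were not called there either. Rpl5 was called at a smaller change than in the class (-0.26, adjusted p = 0.0423). In as many cells drawn from the class, Rpl8, Rps6 and Rpl5 were all called (adjusted p = 3.0e-17, 2.6e-13 and 9.2e-15). As lists in cluster 14 with the preset correlation, MHC class II genes stayed lower in neonatal cells (adjusted p = 7.4e-04), while MHC class I presentation genes were lower (adjusted p = 0.0146) and oxidative phosphorylation genes higher (adjusted p = 7.4e-04), both opposite to the class. With an estimated correlation none of these 3 was called there (adjusted p = 0.414, 0.414 and 0.491).

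**Figure D3:**
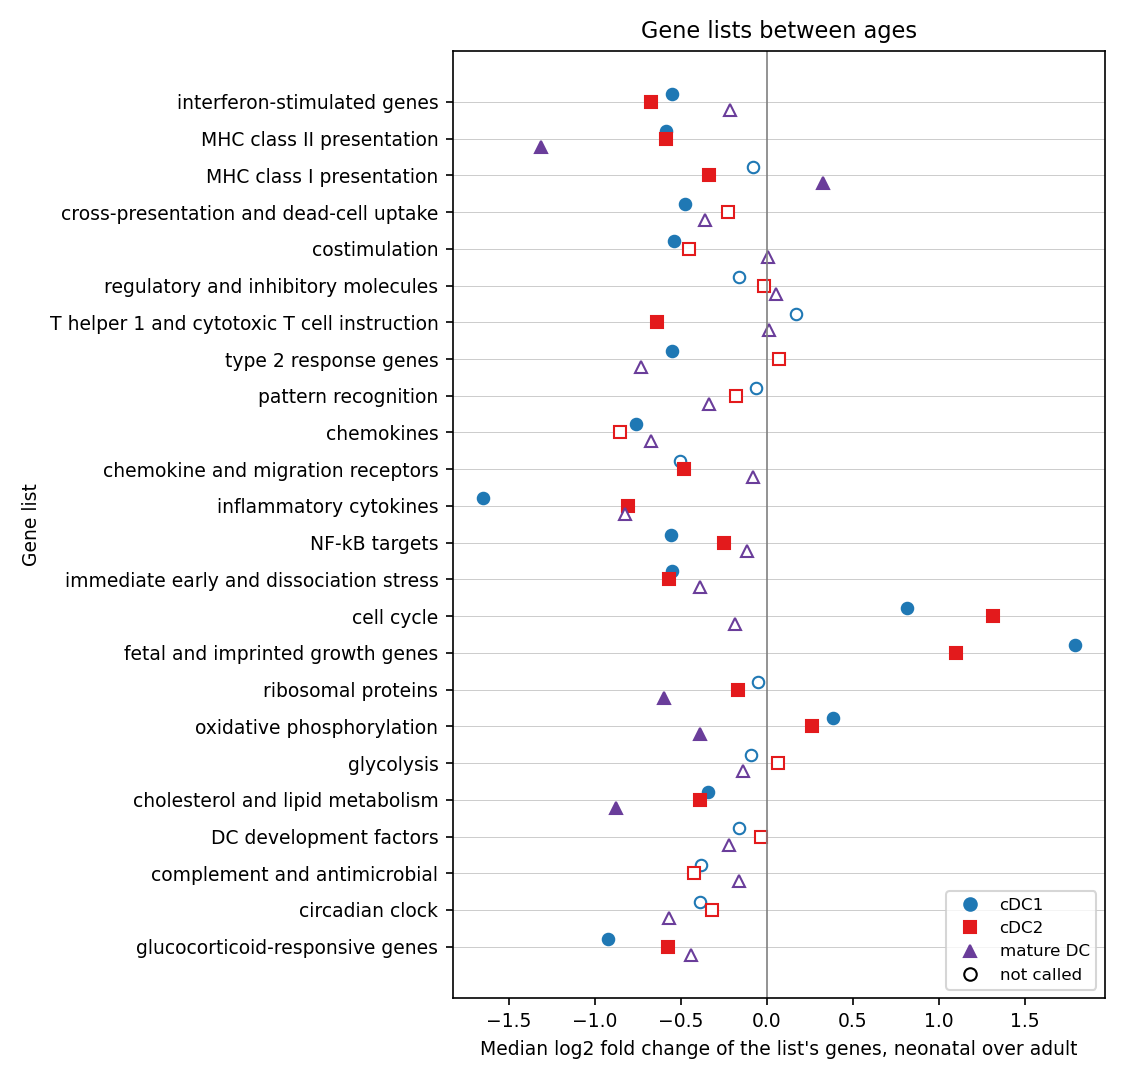
Median log2 fold change, neonatal over adult, of 24 gene lists in cDC1, cDC2 and mature DC; filled symbols are lists called by camera with its preset correlation. MHC class II medians lay at -0.59, -0.59 and -1.32 in the 3 classes, and the mature DC symbols for MHC class I and oxidative phosphorylation take the opposite sign within cluster 14.

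**Figure D4:**
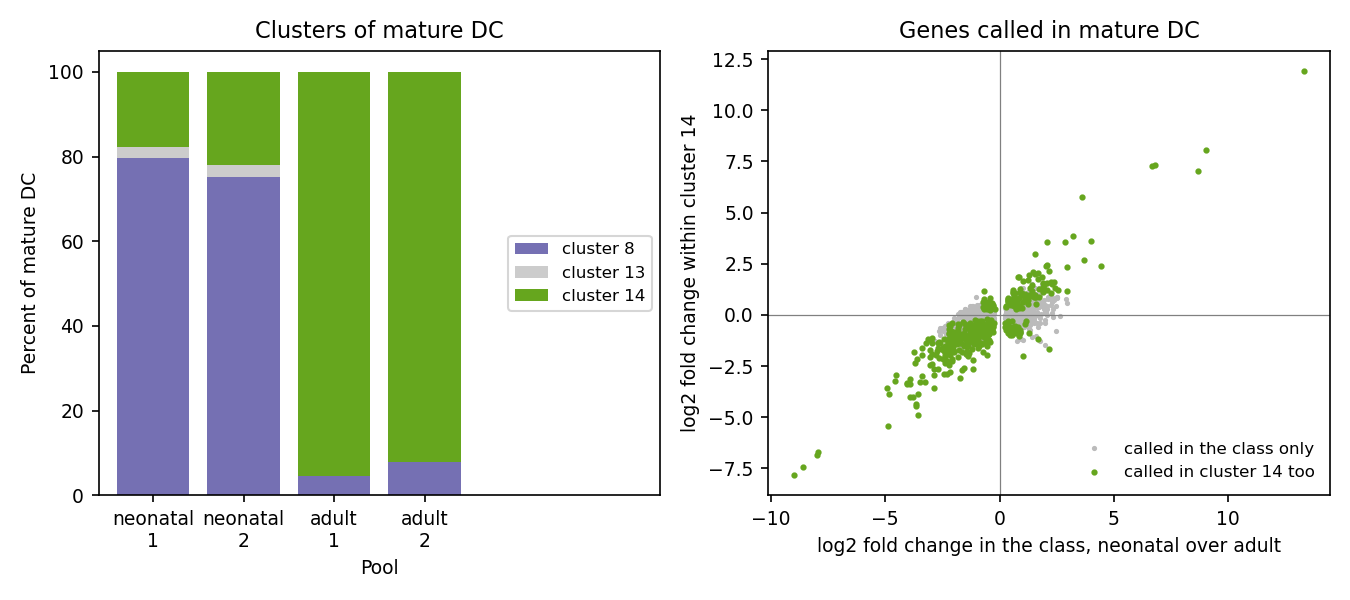
Left, percent of mature DC of each pool in clusters 8, 13 and 14; right, log2 fold change of genes called in mature DC in the class and within cluster 14, 1 point per gene. Of the genes called in both, 377 of 437 had the same sign, and the 2 fits share cells.

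All DC were summed as well, which mixes age effects within classes with the shares of classes. Of 11176 genes tested, 3476 were called, 1633 higher in neonatal and 1843 higher in adult. Among them 1043 changed by 2-fold or more, 488 of them higher in neonatal and 555 higher in adult. Both pools of 1 age lay above both of the other for 67.5% of the genes tested, where chance gives 33.3%, and 4497 genes had an unadjusted p under 0.05. Higher in neonatal DC were Igf2bp3 (4.13 ± 0.24), Yes1 (4.50 ± 0.20), Sox4 (3.20 ± 0.43) and Tcf7 (2.65 ± 0.24), and higher in adult DC Pcdh7 (-7.81 ± 0.28), Barx2 (-4.80 ± 0.23), Mrc1 (-3.49 ± 0.14), Klrd1 (-3.20 ± 0.08) and Timd4 (-3.15 ± 0.13). Of 25 lists, 16 were called, 3 higher and 13 lower in neonatal DC, none with an estimated correlation and 18 by fry. MHC class II genes had 0 higher and 13 lower of 19 tested, or 1 and 14 adjusted over the list alone (median -0.66, camera adjusted p = 2.8e-06, adjusted p = 0.356 with an estimated correlation). Cd74 (-0.81 ± 0.03) and H2-Eb1 (-0.88 ± 0.03) were among them. Interferon-stimulated genes had 3 higher and 22 lower of 42 tested, or 3 and 26 adjusted over the list alone (median -0.67, camera adjusted p = 1.5e-05, adjusted p = 0.356 with an estimated correlation). Ifitm3 (-1.91 ± 0.06) was among them. Cell cycle genes had 38 higher and 1 lower of 46 tested, or 40 and 1 adjusted over the list alone (median 1.06, camera adjusted p = 1.9e-13, adjusted p = 0.356 with an estimated correlation). Mki67 (1.71 ± 0.11) and Uhrf1 (1.57 ± 0.16) were among them. MHC class I genes had 9 higher and 7 lower of 22 in the sum (adjusted p = 0.687). The erythroid marker list was called (camera adjusted p = 0.00813, adjusted p = 0.467 with an estimated correlation), with Hba-a2 (5.54 ± 0.62) and Hbb-bs (6.46 ± 0.71), which are close copies of other globin genes, higher in the neonatal DC sums. Whether DC themselves expressed these globin genes was not tested. Hbb-bs lost its call with no low-count filter (log2 6.48, adjusted p = 0.0598), a fold of 1.5 as the null (adjusted p = 0.0997) and without adult pool 2 (log2 5.85, adjusted p = 0.291). In thinned cells Hba-a2 (log2 7.99, adjusted p = 0.127) and Hbb-bs (log2 6.76, adjusted p = 0.243) both lost it.

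The age effects of cDC1 and cDC2 were compared in 1 fit with pool as a block. They differed for 667 of 9747 genes. The log2 of neonatal over adult was greater in cDC1 for 277 and in cDC2 for 390 of them, whichever class held the change. The unadjusted count was 1612. Il1rl2, the IL-36 receptor gene, rose with age in cDC1 and fell with age in cDC2, at 0.489 against 12.6 CPM in cDC1 and 83.2 against 27.8 in cDC2 (neonatal against adult; log2 difference -6.01 ± 0.50, adjusted p = 4.9e-21). Creb5 stood at 0.393 against 19.6 CPM in cDC1 and 71.0 against 65.4 in cDC2 (-5.47 ± 0.47), Pcdh7 at 0.192 against 78.4 CPM in cDC1 and 0.611 against 1.06 in cDC2 and Enah at 1.58 against 3.57 CPM in cDC1 and 47.0 against 1.69 in cDC2. Pcdh7, with 2 UMIs each in neonatal cDC1 and in cDC2 of both ages, Enah, with 3 in adult cDC2, and Cxcr2, with 0 in adult cDC2, set no size of difference. The log2 of neonatal over adult was greater in cDC1 than in cDC2 for Ecm1 (4.47 ± 0.56), Rasgrp3 (3.24 ± 0.42) and Cx3cr1 (3.14 ± 0.58), and for F13a1 (adjusted p = 2.7e-04) and Pla2g7 (adjusted p = 6.5e-04), which had 2 UMIs each in adult cDC1 and set no size. For F13a1 and Rasgrp3 the change was mostly an adult excess in cDC2, at 0.964 against 0.491 CPM in cDC1 and 2.67 against 43.4 in cDC2 and at 60.6 against 42.6 CPM in cDC1 and 3.58 against 21.8 in cDC2. Several of these calls were lost in alternatives, given with the fitted log2 difference and adjusted p. Without neonatal pool 1 this was so for F13a1 (3.26, 0.675), and without neonatal pool 2 for Pcdh7 (-3.12, 0.986). Without adult pool 1 it was so for F13a1 (3.92, 0.275) and Pcdh7 (-11.89, 0.0728), and without adult pool 2 for Pla2g7 (3.36, 0.112) and Pcdh7 (-6.32, 0.146). At resolution 2 Ecm1 (1.28, 0.453), Pla2g7 (2.06, 0.350) and Pcdh7 (-6.36, 0.108) were not called, nor was Pcdh7 (-6.14, 0.155) with at most 5% mitochondrial UMIs. In thinned cells F13a1 (9.21, 0.261), Ecm1 (5.07, 0.0540), Rasgrp3 (2.99, 0.147), Cx3cr1 (1.70, 0.760) and Pcdh7 (-7.50, 0.200) were not.

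Shared effects were counted over the 8084 genes tested in both classes. Higher in neonates in both were 275 genes, where independent lists of 1012 and 506 genes would share 63.3. Lower in both were 491, where lists of 1284 and 737 would share 117, and 52 were called in opposite directions. The fold changes correlated at r = 0.516 across genes, which are not independent replicates. Both classes came from the same pools, and part of the excess may come from that.

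**Figure D5:**
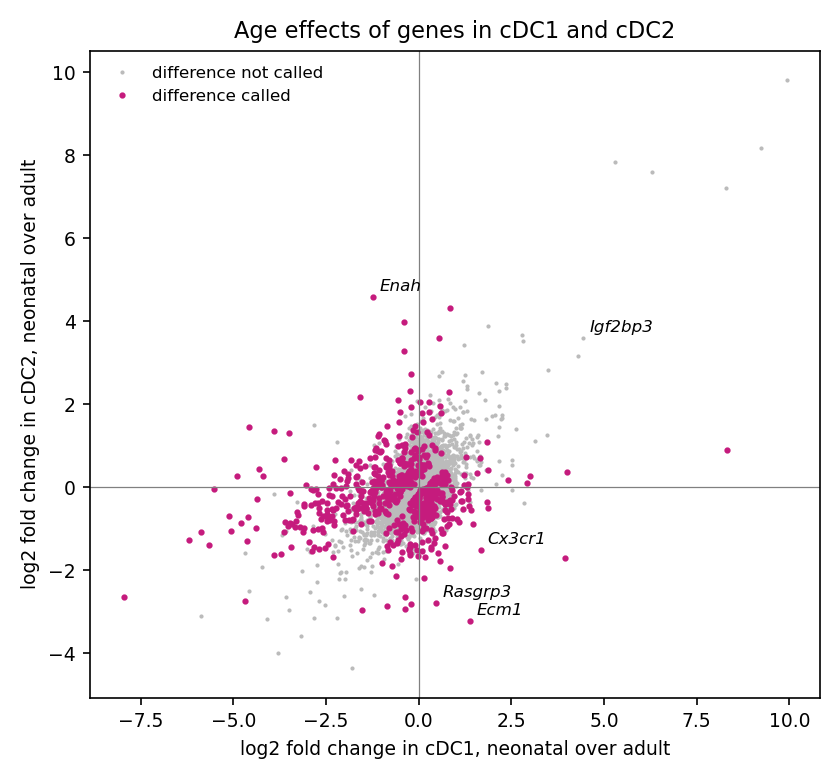
Log2 fold change, neonatal over adult, in cDC1 (horizontal) and cDC2 (vertical), 1 point per gene; coloured points are genes whose difference between the classes was called, and values past 5 rest on few counts in 1 age. Enah and Rasgrp3 lie on opposite sides of 0 for cDC2, at 4.58 and -2.79.

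Proliferation was read from UMIs of Mki67 or Top2a after thinning every cell to 1500 UMIs. They were found in 10.7% ± 0.334 of neonatal and 4.27% ± 1.39 of adult DC (exact permutation p = 0.333, the smallest possible), with median depths before thinning of 6084 and 7486 UMIs. The shares were 13.05% ± 0.103 of neonatal and 5.63% ± 3.06 of adult cells of the cDC1 lineage, 14.5% ± 0.561 of neonatal and 4.94% ± 0.516 of adult cells of the cDC2 lineage and 4.39% ± 0.325 of neonatal and 0.775% ± 1.10 of adult mature DC. With 3 or more UMIs over the cell cycle list, mature DC gave 2.49% ± 0.166 in neonatal and 3.21% ± 2.04 in adult pools, the opposite order (exact permutation p = 1). Nonclassical monocytes, taken as a background of cells held not to divide, gave 2.10% ± 0.167 of neonatal and 0.370% ± 0.524 of adult cells. Their median depths were 2611 and 2903 UMIs, and no share was tested against them. Their ratio of neonatal to adult share (5.66) was as large as that of mature DC (5.66). Both ratios rest on 0 to 2 positive cells per adult pool. The background thus moved with age too, so the mature DC difference cannot be told from it.

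Zbtb46 itself, the gene behind the sort, was not called between ages. It stood at 72.5 ± 6.56 CPM in neonatal and 69.4 ± 4.48 in adult cDC1 (log2 0.00 ± 0.10, adjusted p = 0.997), at 45.2 ± 0.819 CPM in neonatal and 41.3 ± 6.23 in adult cDC2 (log2 -0.02 ± 0.21, adjusted p = 0.964) and at 93.4 ± 9.32 CPM in neonatal and 88.1 ± 12.1 in adult mature DC (log2 0.01 ± 0.16, adjusted p = 0.985). In mature DC it stood lower in neonatal cells, without a call, when cells were thinned (log2 -0.70, adjusted p = 0.205) and within cluster 14 (log2 -0.68, adjusted p = 0.0620). In the classes that are not DC and were tested between ages, its mean was at most 5.61 CPM, in neonatal nonclassical monocytes. It was not read in the endothelial cells, B cells and alveolar macrophages of the sort.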

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

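The tests of clusters with pools kept apart, of cDC2 cells among adult cDC1 as given here, and of free RNA behind cDC2 markers were chosen only after such results were seen. The tests of sex, channel and cluster origin were fixed before theirs.

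Age effects that differed between cDC1 and cDC2 in a test of the difference itself stood out for 667 genes. As log2 of neonatal over adult in cDC1 minus that in cDC2, the named ones were F13a1 (5.19), Ecm1 (4.47), Pla2g7 (3.55), Rasgrp3 (3.24), Cx3cr1 (3.14), Cxcr2 (-10.08), Pcdh7 (-7.18), Il1rl2 (-6.01), Enah (-5.87) and Creb5 (-5.47). The changes of Pcdh7 and Creb5 lay in cDC1 and those of F13a1 and Rasgrp3 mostly in cDC2, in each case as an adult excess. F13a1, Pla2g7, Pcdh7, Enah and Cxcr2 rest on 0 to 3 UMIs in an age of a class and set no size. No explanation was tested for these differences.

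The sort also held cells outside the DC comparisons, and they too differed between ages. Genes called numbered 668 in NK cells, 591 in T or innate lymphoid cells, 181 in basophils or mast cells, 1346 in classical monocytes, 1858 in neutrophils and 1742 in nonclassical monocytes.

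The 2656 genes called in cDC1 were weighed against sex, channel and clusters. A shift of the loading channel common to all cells cannot be told apart from age. These genes moved in 6 classes that are not DC by a median of 0.33 of their change in cDC1. The upper quartile was 0.788. The genes were chosen for their change in cDC1, so a smaller change in other classes is in part built in. The median was positive in each of the 6 classes, so a part shared by all cells stays open. With the preset correlation, immediate early and dissociation stress genes were lower in neonatal cells of these 6 classes too. Different clusters cannot be told apart from age: with the class taken from the pools of 1 number and cluster 0 from the others, the change within cluster 0 was a median of 0.733 and 0.713 of that in the class. This was 0.648 and 0.80 of what as many cells drawn from the class gave, where over 0.75 in both orders was set to exclude clusters and under 0.25 to support them. Sex cannot be told apart from age: in neonatal pool 2 the 89 cells with Y-linked UMIs were shifted toward adult by -0.0035 of the age effect, but neonatal pool 1 had 2 such cells, and age itself stays an untested explanation.

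Of the cDC2 markers, 13 were higher in adult cDC1, which cDC2 cells sorted into the class may explain in part. Against such cells as the cause of the whole, 15 other abundant cDC2 genes rose in adult cDC1 over neonatal cDC1 by a median of 3.04% of their cDC2 level (upper quartile 9.24%), where the 13 markers rose by a median of 19.1%. The 13 markers were chosen for being higher in adult cDC1 and the 15 genes were not, so the gap between the medians is in part built in. Among the 13, Cd24a, Clec12a and, by little, Ltb4r1 stood higher in adult cDC1 than in adult cDC2 at resolution 2. Klrd1 stood higher in adult cDC1 only against the cDC2 class as tested. The cDC2 level was taken at resolution 2, where macrophage-like cells form a cluster of their own, and markers that rose little, such as Cd209a (3.61%) and Mgl2 (0.803%), stay open to cDC2 cells. Free RNA could supply at most 26.3% of the adult level, for Il1b, and under 1% for Klrd1 and Clec12a, so for Il1b free RNA and expression cannot be told apart in part. A change of cDC1 themselves with age or sex stays open.

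In mature DC, different clusters at the 2 ages cannot be told apart from age for the 2704 genes called. With the class taken from the pools of 1 number and cluster 14 from the others, the change within cluster 14 was a median of 0.284 and 0.324 of that in the class, or 0.30 and 0.293 of what as many cells drawn from the class gave. Under 0.25 was set to support clusters as the cause and over 0.75 to exclude them. Of causes for the neonatal cells of cluster 8 only an origin from cDC1 was tested, which fell short of its bound (0.84) and stays open, as do age, channel and sex.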

How the results depend on the processing

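Values below for cDC1, cDC2, mature DC and all DC follow that order, and the fits of shared clusters, of equal cell numbers from the class, of free RNA and of C1q, and the estimated correlation within clusters, were chosen after seeing the data. The DESeq2 Wald test called 1253, 404, 1323 and 1767 genes, and 131 for the difference between cDC1 and cDC2. Cells thinned to 1500 UMIs in equal numbers gave 494, 214, 768 and 884, and 99, from fewer counts. A fold of 1.5 as the null gave 697, 261, 987 and 884. Without cycling cells cDC2 gave 856, and at least 20 CPM in 2 sums left 2309 in all DC, where fewer genes are tested. Only the cluster held by both ages gave 525 in cDC1 and 598 in mature DC, and as many cells drawn from the class 958 and 1763. Where the percent of calls higher in neonatal cells moved by over 10 points, it went from 40.6 to 29.7 (DESeq2) and 25.2 (thinned) in cDC2. In cDC1 it went from 44.1 to 28.3 (fold of 1.5) and 33.1 (cluster 0), in mature DC from 48.5 to 35.8 (cluster 14), and for the difference from 41.5 to 25.2 (DESeq2) and 51.7 (resolution 2). Except where stated, the causes were not tested. Apart from leaving out pools, given next, each other alternative stayed within 1.5 times of these counts.

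Leaving out 1 pool assumes that the lone pool varies like the other age. The counts then ran over 2018 to 2205, 654 to 1063, 1825 to 2313 and 2735 to 3124, and over 387 to 482 for the difference. cDC2 fell to 654 without neonatal pool 1 and 773 without neonatal pool 2, and the difference to 401 without neonatal pool 1, 387 without adult pool 1 and 398 without adult pool 2. Lists called ran over 13 to 16, 12 to 14, 6 to 8, with 8 without adult pool 2, and 12 to 14. With an estimated correlation camera called 0 lists in each of the 4 and 0 within clusters 0 and 14, and fry 11 in mature DC. As that setting has little power with 4 sums, the 0 calls decide little about the lists.

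The replicate number paired no pools: deviations of pools with the same number correlated at -0.0216, 0.0912, 0.0635 and -0.00205 across genes, and the number marks no shared animals or day in the labels. As a replicate block it gave 2680, 1274, 2809 and 3364 genes and 14, 15, 7 and 14 lists.

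Differences of shares, in percentage points neonatal minus adult, moved as follows. Neutrophils came to -14.4 at resolution 2. Nonclassical monocytes came to 11.3 with doublets kept and 10.2 at resolution 2. Classical monocytes, at -0.436, reversed to 4.42 with doublets kept, came to -2.37 at resolution 2, and ran over -0.998 to 0.126 when pools were left out, with the highest value without neonatal pool 2. cDC2 came to -8.21 with the loose cell filter, and mature DC to 11.8 and 11.5 at resolutions 0.5 and 2. Without neonatal pool 2 the cDC2 difference was -2.79, and without adult pool 1 the cDC1 difference was -4.31. The proliferation difference was 5.92 at 1000 UMIs, 9.28 at the deeper thinning, 9.01 not thinned and 8.50 over the cell cycle list for all DC. For the cDC1 lineage these were 7.04, 10.0, 10.9 and 11.8, and for the cDC2 lineage 9.36, 14.04, 16.6 and 18.5. In mature DC it went from 3.61 to 2.30, 4.39, 2.24 and -0.717 in the same order.

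Over 4315 alternative values of 220 gene results, 4149 kept direction and call, 133 kept direction and lost the call, and 33 changed sign. Results without a value in an alternative are not in these counts. In thinned cells 139 kept direction and call, 18 lost the call and 2 changed sign, and the rest of the 220 gave no value. Calls most often lost were those of Ecm1 and Fabp5 in cDC2 and of Pcdh7 between cDC1 and cDC2. Thinned cells lost those of Ifi203, Cd86, Cd83, Tnfsf13b and Dut in cDC1 and of Ifngr1, Nfkbiz and Atp5g3 in cDC2, and doublets kept that of Birc5 in cDC2. Fabp5 in cDC2 went to -0.63 at resolution 2 and was called in this opposite direction (adjusted p = 1.0e-06). Within cluster 0, Socs3 and Cxcl16 in cDC1 went to 0.12 and 0.34. Within cluster 14, Tapbp went to -0.28, H2-Q4 to -0.82, Il15ra to -0.0186, Il4ra to -0.40, Abcg1 to -0.20 and Irf8 to -0.40. Clusters were drawn from the same expression values, so neonatal cells of cluster 14 may be those nearest to adult cells. Zbtb46, near 0 in each class as reported and never called, changed sign most often. It took -0.00501, -0.0256, -0.0755 and -0.17 in cDC1, with at least 20 CPM, doublets kept, the loose filter and fewer cells. In cDC2 it took 0.0122, 0.0632, 0.0157, 0.0283 and 0.0154 with no filter, doublets kept, thinned cells, no cycling cells and no C1q-positive cells. In mature DC it took -0.0479, -0.00388, -0.0624, -0.0379, -0.70, -0.00560, -0.68 and -0.0143 with doublets kept, the loose filter, resolutions 0.5 and 2, thinned cells, ribosomal genes left out, cluster 14 alone and fewer cells. With 1 pool left out it ran over -0.0898 to 0.0888, -0.16 to 0.13, -0.12 to 0.15 and -0.14 to 0.0853. The alternative for ages whose pools cannot be told apart was not run, since the pools could be.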

Other observations

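The 6 classes that are not DC were not among the comparisons fixed beforehand, and their genes are given as neonatal against adult means of 2 pools. The monocytes and neutrophils also fell into different clusters, with 98.3% of neonatal classical monocytes in cluster 7 and 93.3% of adult ones in cluster 24. Of neonatal nonclassical monocytes 49.6% and 49.7% lay in clusters 3 and 5, and 97.9% of adult ones in cluster 4. Of neonatal neutrophils 76.6% lay in cluster 1 and 22.8% in cluster 11, and 99.9% of adult ones in cluster 23, and no comparison was made within these clusters. Neonatal neutrophils expressed the granule genes Ltf (3649 against 0.573 CPM), Camp (10755 against 4.11 CPM) and Ngp (10612 against 7.28 CPM), made early in neutrophil maturation. All 3 were leading genes of cluster 11 and not of the larger cluster 1. Adult neutrophils expressed more Cxcr1 (0.440 against 26.3 CPM), Isg15 (52.4 against 396 CPM) and Rsad2 (18.1 against 120.4 CPM), and interferon-stimulated genes as a list had 1 higher and 23 lower of 33 (median -0.99, camera adjusted p = 3.5e-09, adjusted p = 0.538 with an estimated correlation). Classical monocytes, for which free RNA was not bounded, expressed Igf2bp3 in neonates (62.3 against 0.398 CPM), as did neonatal DC, and in adults the class II genes H2-Aa (-3.60 ± 0.10), H2-Ab1 (-3.47 ± 0.07) and Cd74 (-3.24 ± 0.05). In them interferon-stimulated genes had 0 higher and 34 lower of 46 (median -0.79, camera adjusted p = 1.1e-15, adjusted p = 0.298 with an estimated correlation) and MHC class II genes 1 higher and 9 lower of 14 (median -0.87, camera adjusted p = 4.9e-07, adjusted p = 0.226 with an estimated correlation). Nonclassical monocytes differed in Nes (4.67 ± 0.39), higher in neonates, and in Fabp4 (-3.41 ± 0.10) and Chil3 (-4.60 ± 0.34), higher in adults.

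Adult NK cells expressed more of the receptor gene Klra4 (27.1 against 1057 CPM), of a family of close copies, and neonatal NK cells more Cxcr6 (67.6 against 2.60 CPM). Cd3d (71.4 against 3.90 CPM), a leading gene of T cell cluster 6, was higher in neonatal NK cells as well, and T or innate lymphoid cells within this class are not excluded. In NK cells cell cycle genes had 15 higher and 0 lower of 34 (median 1.82, camera adjusted p = 5.9e-12, adjusted p = 0.782 with an estimated correlation). T or innate lymphoid cells of adults expressed more of the chemokine gene Ccl5 (-4.89 ± 0.19) and the cytotoxic gene Prf1 (-4.44 ± 0.49), and also of the NK receptor genes Klre1 (-5.96 ± 0.54) and Klrk1 (-4.95 ± 0.44), so that NK cells within this class are not excluded. The recombinase gene Rag1 came to 140.1 against 0 CPM in this class, and cluster 21, which held it, had 27, 13, 0 and 0 cells in neonatal pools 1 and 2 and adult pools 1 and 2. Mast cell protease genes Cma1 (761 against 0 CPM) and Mcpt4 (419.7 against 0 CPM) marked the neonatal basophil or mast cells. Alveolar macrophages formed a cluster of 54, 41, 0 and 0 cells. Cluster 15, left unnamed and led by Adamdec1, Hmox1, Spic, Clec4n and Axl, had 44, 47, 0 and 0. Immediate early and dissociation stress genes had 0 higher and 25 lower of 28 (5.0e-15 and 0.192) in classical monocytes, 3 higher and 20 lower of 28 (5.8e-05 and 0.466) in neutrophils, 2 higher and 15 lower of 28 (5.4e-04 and 0.488) in nonclassical monocytes, 1 higher and 9 lower of 24 (0.00170 and 0.782) in NK cells, 1 higher and 10 lower of 24 (0.00184 and 0.519) in T or innate lymphoid cells and 1 higher and 10 lower of 21 (0.0155 and 0.486) in basophils or mast cells. The values in brackets are camera adjusted p with the preset and with an estimated correlation, and none of the 6 was called with the latter.

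A hypothesis fixed before its test was that mature DC of cluster 8 may derive from cDC1 and those of cluster 14 from both cDC1 and cDC2. Within the neonatal pools, cDC1 markers stood higher in cluster 8 than cDC2 markers did, relative to cluster 14, by 0.84 (log2) in the lower pool and 0.893 in the other. Of the cDC1 markers 9 of 16 and 10 of 15 were higher in cluster 8, and of the cDC2 markers 5 of 12 in both pools. Irf8 (2.85 and 3.05), Cadm1 (1.03 and 2.00), Xcr1 (0.504 and 0.370) and Clec9a (0.641 and 1.75) were higher. Irf4 (-1.21 and -0.85) and Sirpa (-1.52 and -2.05) were lower. Against this, the cDC1 gene Wdfy4 (-1.67 and -1.24) was lower and the cDC2 gene Itgam (0.32 and 0.63) higher. The difference fell short of the bound of 1 set beforehand, and mature DC lose most markers of their origin, so the hypothesis stays open.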
